A study of Mus musculus with 12 samples.

How the data were processed

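RNA was measured in CD4+ T cells of mouse spleen, from wild-type C57BL/6J mice (WT) and from mice without Sirt2 (KO), either directly after isolation (0 h) or after 24 h on plate-bound anti-CD3 antibody at 5 µg/ml. Sirt2 encodes an NAD-dependent protein deacetylase. The cells were enriched by removing other cell types, and per the labels flow cytometry put their purity above 95%. Per the labels' protocols, libraries of total RNA were made from 100 ng of RNA with a NuGen Ovation Mouse kit and ribosomal RNA was reduced with probes. The 12 libraries fell into 4 groups of 3, named here WT 0 h, KO 0 h, WT 24 h and KO 24 h. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

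The values were read counts per gene symbol, 1 column per library, as deposited. The submitters' processing notes name the aligner STAR 2.6.0c, DESeq and the build hg19. That build is human while the symbols of the counts are those of mouse genes, so the build behind the counts is uncertain and no coordinates are printed. The counting program, the annotation and the strand setting are not given in the sources used here. Each table had 23479 gene symbols and 5 closing entries that name no gene, and these were left out of library sizes and tests. Of all reads listed, 22.8% to 35.4% stood in the entry for no feature, 0.412% to 0.576% in that for ambiguous reads and 25.7% to 30.9% in that for reads aligned to several places. Genes with near-identical copies, such as the Gbp, Ly6, histone and ribosomal protein families, Fbxo17 with Fbxo27, and Tpi1 with its pseudogenes, are therefore uncertain, because reads that match several copies were not counted for any gene. With no strand setting stated, genes that overlap another gene are uncertain too. By exon overlap in the GENCODE mouse annotation, these were Sirt2 with Nfkbib, Txnip with Gm15441, Zfp36 with Gm44710, Gramd1a with Gm10640, Tpi1 with Spsb2, Pde2a with Gm45837, and Hist1h1e with Hist1h2be and Gm11398. The RefSeq table of assembly GRCm38 was used for chromosomes and for the order of genes along them. Of the symbols, 21692 matched it directly, 1582 by a synonym and 205 not at all.

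Reads in genes ranged from 3.63 to 10.0 megareads per library. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), and levels are given as CPM, counts scaled by library size and these factors, as mean ± SD with n = 3. Genes were kept by filterByExpr over the 4 groups with a minimum count of 10 and a minimum total of 15, which left 10981. The test was edgeR's quasi-likelihood test with robust dispersion, in 1 fit of the 4 groups without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene passed at an adjusted p below 0.05. The biological coefficient of variation was 0.115. There were 5 comparisons: KO against WT at 0 h, KO against WT at 24 h, 24 h against 0 h in WT, 24 h against 0 h in KO, and the interaction of genotype and time. All fold changes are on the log2 scale, with the standard error (SE) of the fit.

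Before the data were examined, the tests, the rule for naming genes, 38 gene lists and all alternatives except 1 were fixed. The rule named Sirt2 in every library. For each comparison it named the genes with the largest changes among those that passed, reached a mean of 5 CPM in a group compared and had no overlap between the libraries of the groups compared. These were up to 10 per direction between genotypes and up to 6 per direction over time and for the interaction, where no overlap condition was set. Predicted genes and segments of T cell receptor and immunoglobulin genes were left out. Of each list it named up to 4 members with the largest changes among those that passed or, where none passed, up to 2 with the highest mean level. Some genes that the rule names are not reported here. Lists covered metabolism, T cell activation and differentiation, cell cycle, ribosomes, stress, interferon-stimulated genes, histones, genes near Sirt2, sirtuins, strain and sex markers, and markers of T cells and of other spleen cells. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 30 lists with at least 3 tested members. Camera asks whether a list's genes lie higher or lower than the other genes. Each list was also tested with an estimated correlation and with fry. The passing members of each list were counted again with p-values adjusted over the list alone. A fold against a group without a read was computed against 3 counts over the group and is given as a lower bound, and with 1 to 3 reads as a ratio of reads scaled by library size with its 95% exact counting interval. Intervals and floors cover counting error only. Transcripts encoded by the mitochondrial genome were not analysed here.

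Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter at 1 CPM in at least 3 libraries, leaving out structural RNA, haemoglobin and immunoglobulin genes, fitting only the groups compared, the replicate number as a block, for all comparisons and within genotypes, and leaving out each library in turn. Leaving out the genes of chromosome 7 was added after seeing the data. The pipeline was tested on simulated counts for the 10981 genes with 200 changed. For KO against WT at 0 h it recovered 58.2% of 1.5-fold, 77.6% of 2-fold and 92.4% of 4-fold changes, and 4.79% of its calls were false. For KO against WT at 24 h the shares were 40.3%, 76.1% and 97%, with 5.66% false. For the response over time they were 55.2%, 79.1% and 93.9% in WT, with 3.57% false, and 43.3%, 80.6% and 92.4% in KO, with 6.96% false. For the interaction they were 26.9%, 59.7% and 86.4%, with 9.23% false. A list shifted by 1.3-fold was called in each of the 5 simulated comparisons and 0 of 29 lists without a shift were. The simulated genes varied independently, so the simulation cannot show how often camera calls unchanged lists whose genes vary together. In the data at 0 h the estimated correlation was 0.294 for T cell activation and 0.502 for ribosomal proteins.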

Results

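CD4+ T cells from the spleens of WT and Sirt2 KO mice were compared before and after 24 h of stimulation through CD3, a chain of the T cell receptor complex. The design asks what loss of the deacetylase SIRT2 changes in T cells taken from the animal and in activated ones, and the title of the series places the question in T cell metabolism. Each of the 4 groups had 3 libraries. Reads in genes, in megareads (M), were 7.60 ± 1.19 M in WT 0 h (SD, n = 3), 7.45 ± 2.24 M in KO 0 h, 6.56 ± 1.71 M in WT 24 h and 4.61 ± 0.879 M in KO 24 h. Depth was lower on average in KO 24 h than in WT 24 h (two-sided exact permutation p = 0.3) and lower in every KO 24 h library than in every KO 0 h library (two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 can give). The ribosomal RNA precursor Rn45s took 14.5% ± 1.41 of gene reads in WT 0 h, 14.7% ± 2.51 in KO 0 h, 9.12% ± 0.416 in WT 24 h and 8.04% ± 0.106 in KO 24 h. At 24 h its share was lower in every KO library than in every WT library (two-sided exact permutation p = 0.1, the smallest possible). Counts of every pair of replicates differed by more than sampling noise, with a chi-square per gene of 3.24 to 15.7. The first principal component of log CPM, with 61.5% of the variance, parted the 0 h from the 24 h libraries. The next, with 5.84%, placed the 6 KO libraries on one side and the 6 WT libraries on the other.

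Sirt2 RNA was low in every KO library. Its level was 74.6 ± 9.42 CPM in WT 0 h and 12.5 ± 3.59 CPM in KO 0 h, which was 16.7% of WT. At 24 h it was 67.2 ± 7.92 CPM in WT and 13.2 ± 5.6 CPM in KO, which was 19.7% of WT. The single libraries had 70.5, 67.9 and 85.4 CPM in WT 0 h, 12.1, 9.04 and 16.2 CPM in KO 0 h, 62.3, 62.9 and 76.3 CPM in WT 24 h, and 9.52, 10.5 and 19.7 CPM in KO 24 h. The log2 fold change of Sirt2 in KO was -2.60 at 0 h (SE 0.189, edgeR QL, BH-adjusted p = 7.69e-11) and -2.39 at 24 h (SE 0.196, edgeR QL, BH-adjusted p = 1.25e-09). Sirt2 did not pass the test over time in WT (log2 -0.15, edgeR QL, BH-adjusted p = 0.487) or in KO (log2 0.06, edgeR QL, BH-adjusted p = 0.869). The sources used here do not say which part of the gene was removed, and gene totals cannot show where the remaining reads lay. Sirt2 shares its locus with Nfkbib, so some of them could not be assigned with certainty without strand.

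**Figure D1:**
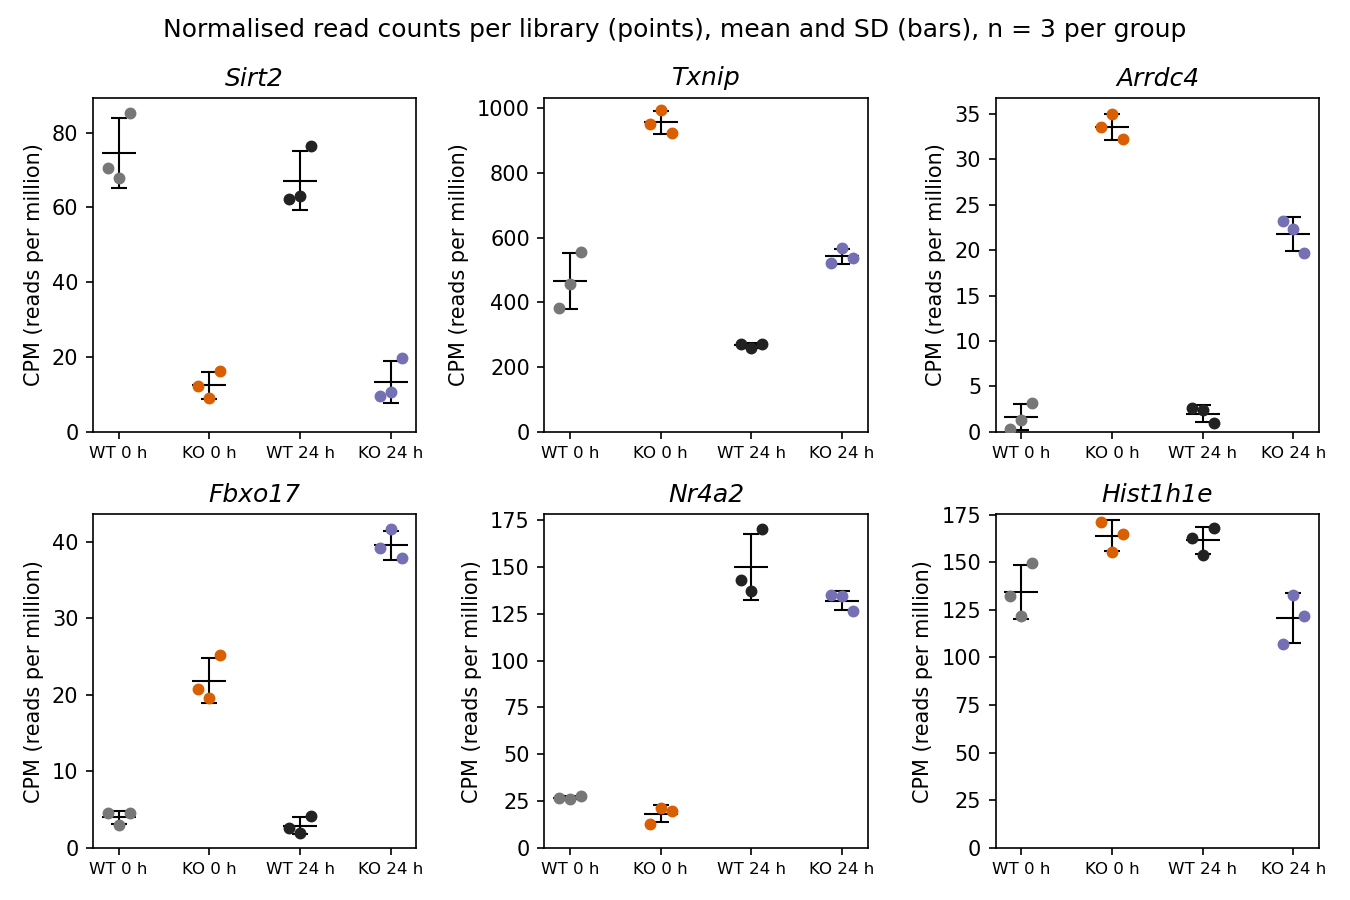
Normalised read counts in CPM (y axis, from 0) of Sirt2, Txnip, Arrdc4, Fbxo17, Nr4a2 and Hist1h1e in the 4 groups (x axis). Points are single libraries, and bars give the mean and SD with n = 3. Sirt2 was lower in every KO than in every WT library, while Txnip, Arrdc4 and Fbxo17 were higher at both times.

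Ex vivo KO T cells had more RNA of Txnip and Arrdc4 and less RNA of several genes of T cell activation than WT cells. Arrdc4 and Txnip encode related alpha-arrestins that restrain glucose uptake. Arrdc4 rose from 1.57 ± 1.42 CPM in WT to 33.6 ± 1.41 CPM in KO (log2 4.30, SE 0.308, edgeR QL, BH-adjusted p = 4.79e-13), and Txnip rose from 465 ± 86.8 to 956 ± 36.0 CPM (log2 1.04, SE 0.0925, edgeR QL, BH-adjusted p = 7.69e-11). The neighbouring F-box genes Fbxo17 and Fbxo27, close to Sirt2 on chromosome 7, rose too. Fbxo17 had 21.9 ± 2.99 CPM in KO and 4.02 ± 0.841 CPM in WT (log2 2.44, SE 0.234, edgeR QL, BH-adjusted p = 4.78e-10), and Fbxo27 had a log2 fold change of 2.55 (SE 0.520, edgeR QL, BH-adjusted p = 0.00936). Further rises were in Wfikkn2, which encodes a secreted protease inhibitor domain protein (log2 1.57, SE 0.257, edgeR QL, BH-adjusted p = 0.000366), the small GTPase gene Rhob (log2 0.68), Ly6a (log2 0.56) and Ly6c1 (log2 0.50), which encode surface antigens of lymphocytes, and Pde2a (log2 0.55), which encodes a cyclic nucleotide phosphodiesterase. Cd8b1, a marker of CD8 T cells, rose from 17.4 ± 0.392 to 31.5 ± 1.83 CPM (log2 0.85, SE 0.185, edgeR QL, BH-adjusted p = 0.0176). The largest fall beside Sirt2 among the named genes was in Cd22, a B cell marker that went from 7.41 ± 2.92 to 1.32 ± 0.136 CPM (log2 -2.49, SE 0.519, edgeR QL, BH-adjusted p = 0.0118). It was followed by the peptidase gene Pepd (log2 -1.24, SE 0.215, edgeR QL, BH-adjusted p = 0.000966) and the transcription factor gene Klf9 (log2 -1.06, SE 0.213, edgeR QL, BH-adjusted p = 0.00851). Rab11fip3 (log2 -0.94), Arc (log2 -0.83), the ETS repressor gene Erf (log2 -0.68) and Dedd2 (log2 -0.67) fell as well.

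Genes of T cell activation were lower as a list in ex vivo KO cells. Of its 22 tested members 4 fell, 0 rose and 18 did not pass, and with p-values adjusted over the list alone 10 fell. The members that fell were Nfkbid, a regulator of NF-kappaB (log2 -0.82, SE 0.115, edgeR QL, BH-adjusted p = 1.62e-05), and the orphan nuclear receptor gene Nr4a2 (log2 -0.59, SE 0.143, edgeR QL, BH-adjusted p = 0.0447). The others were Myc, a driver of growth that went from 292 ± 29.7 to 206 ± 43.6 CPM (log2 -0.50, SE 0.107, edgeR QL, BH-adjusted p = 0.0236), and Irf4, a transcription factor of activated lymphocytes (log2 -0.42, SE 0.103, edgeR QL, BH-adjusted p = 0.0494). The list median was -0.294 (camera, BH-adjusted p = 6.34e-11), and adjusted p = 0.159 with an estimated correlation. Immediate-early and cell isolation stress genes were lower as well, with a median of -0.274 over 15 members (camera, BH-adjusted p = 1.44e-06) and adjusted p = 0.159 with an estimated correlation. Of these 1 fell, the RNA-decay gene Zfp36 (log2 -0.47, SE 0.0834, edgeR QL, BH-adjusted p = 0.00136), and 7 fell with p-values adjusted over the list alone. In the list of ribosome biogenesis 0 of 25 members passed, 3 fell with p-values adjusted over the list alone, and the median was -0.137 (camera, BH-adjusted p = 0.000749, and adjusted p = 0.159 with an estimated correlation). Ribosomal proteins had a median of -0.0642 with 0 of 79 passed and 1 lower adjusted over the list alone (camera, BH-adjusted p = 0.000207, and adjusted p = 0.791 with an estimated correlation). Naive and quiescent T cell genes lay higher, with 2 of 24 risen, Txnip and Ly6c1, the same number adjusted over the list alone, and a median of 0.066 (camera, BH-adjusted p = 4.82e-06, and adjusted p = 0.0978 with an estimated correlation). Beside these lists stood the changes in Cd8b1 and Cd22, markers of CD8 T cells and B cells. The other CD8 T cell marker, Cd8a, was near the floor and not tested, at 0.680 ± 0.328 CPM in WT and 1.16 ± 0.957 CPM in KO.

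No single gene of the metabolic lists passed at 0 h. Glycolysis had a median of -0.0901 with 0 of 23 passed by either adjustment, adjusted over the list alone included (camera, BH-adjusted p = 0.0479, and adjusted p = 0.669 with an estimated correlation). Gapdh had a log2 fold change of -0.04 and Aldoa of -0.25, and neither passed. No list of mitochondrial metabolism passed, with camera BH-adjusted p of 0.491 for nuclear oxidative phosphorylation subunits (0 of 71 members passed), 0.384 for the TCA cycle (0 of 24) and 0.466 for fatty acid oxidation (0 of 26). The log2 fold change was 0.05 for Atp5b, -0.01 for Atp5a1 and 0.11 for Ogdh. Glutamine and amino acid uptake (0 of 15 passed, 1 lower adjusted over the list alone) had a camera BH-adjusted p of 0.0945, serine and one-carbon metabolism of 0.219, the pentose phosphate pathway of 0.484 (1 of 10 higher adjusted over the list alone) and cholesterol synthesis of 0.762. Other sirtuins did not pass, with log2 0.07 for Sirt1 and -0.03 for Sirt7. By camera with BH adjustment, p was 0.178 for interferon-stimulated genes, 0.484 for regulatory T cell genes, 0.886 for cytokines and chemokines and 0.466 for cytotoxic effector genes. It was 0.886 for inhibitory receptors, with 1 of 13 higher adjusted over the list alone, 0.951 for T helper lineage genes and 0.363 for cell cycle genes, and 0 members of these lists passed. It was 0.0688 for the unfolded protein and integrated stress response (0 of 16 passed, 2 lower adjusted over the list alone), 0.136 for histones (0 of 56) and 0.0688 for T cell markers (0 of 11 passed, 1 higher adjusted over the list alone). Among these markers Cd4 had a log2 fold change of 0.03 and Cd3e of 0.05. The 36 tested genes near Sirt2 held 2 that rose, Fbxo17 and Fbxo27, and 1 that fell, Zfp36 (camera, BH-adjusted p = 0.762). Of 4 tested genes known to differ between C57BL/6J and other strains 0 passed, with Nnt at log2 -0.07.

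At 0 h 38 genes passed in all, 13 higher and 25 lower in KO, and in each the 3 KO libraries did not overlap the 3 WT libraries. Chance gives no overlap in 10% of genes, and 12.4% of all tested genes showed none. At an unadjusted p below 0.05 there were 878, and DESeq2 called 47. When each library of the groups compared was left out in turn, Arrdc4, Fbxo17, Wfikkn2, Txnip, Pepd, Nfkbid and Zfp36 passed each time. Ly6c1 missed the threshold without KO replicate 1 (edgeR QL, BH-adjusted p = 0.0532) and Klf9 without KO replicate 3 (edgeR QL, BH-adjusted p = 0.0977). The other named genes, those of T cell activation except Nfkbid among them, missed it in 2 to 5 of the 6 refits, with BH-adjusted p of up to 0.417 for Nr4a2 and 0.196 for Myc.

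After 24 h of stimulation the same alpha-arrestins and F-box genes were higher in KO. Fbxo17 rose from 2.92 ± 1.15 CPM in WT to 39.5 ± 1.91 CPM in KO (log2 3.76, SE 0.243, edgeR QL, BH-adjusted p = 2e-15). Arrdc4 rose from 2.00 ± 0.892 to 21.8 ± 1.87 CPM (log2 3.46, SE 0.312, edgeR QL, BH-adjusted p = 2.85e-10) and Fbxo27 by log2 3.42 (SE 0.594, edgeR QL, BH-adjusted p = 0.000764). Txnip rose from 267 ± 7.11 to 542 ± 23.6 CPM (log2 1.02, SE 0.0941, edgeR QL, BH-adjusted p = 2.58e-10). Other rises were in Xdh, which encodes a purine-degrading oxidase (log2 1.06, SE 0.207, edgeR QL, BH-adjusted p = 0.00505), and in the amino acid transporter gene Slc43a2 (log2 0.84, SE 0.144, edgeR QL, BH-adjusted p = 0.000699). Adamtsl4 (log2 1.36), Pdlim4 (log2 0.93), Rhob (log2 0.76) and Igsf23 (log2 0.76) rose as well. The falls beside Sirt2 included the zinc finger gene Zfp82 (log2 -2.22, SE 0.479, edgeR QL, BH-adjusted p = 0.0175), the calcium-dependent kinase gene Camk2b (log2 -1.60, SE 0.333, edgeR QL, BH-adjusted p = 0.0106) and Pepd (log2 -1.14, SE 0.230, edgeR QL, BH-adjusted p = 0.00706). The glycolytic enzyme gene Tpi1 fell from 49.6 ± 8.25 to 30.2 ± 3.14 CPM (log2 -0.72, SE 0.155, edgeR QL, BH-adjusted p = 0.0172). The cyclic AMP response gene Crem (log2 -0.72), Rundc3b (log2 -0.67) and Erf (log2 -0.66) fell too. The linker histone gene Hist1h1e fell from 162 ± 7.07 to 121 ± 13.1 CPM (log2 -0.42, SE 0.0959, edgeR QL, BH-adjusted p = 0.0291).

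Of 24 naive and quiescent T cell genes, 3 rose in activated KO cells, also adjusted over the list alone. Among them were Txnip and Ly6c1 (log2 0.67, SE 0.1, edgeR QL, BH-adjusted p = 6.14e-05). The list median was 0.0687 (camera, BH-adjusted p = 0.000141, and adjusted p = 0.132 with an estimated correlation). Of 24 interferon-stimulated genes 1 rose, Ifi27l2a, from 91.7 ± 9.18 to 146 ± 17.6 CPM (log2 0.67, SE 0.106, edgeR QL, BH-adjusted p = 0.00012), 3 rose adjusted over the list alone, and the median was 0.166 (camera, BH-adjusted p = 3.95e-08, and adjusted p = 0.5 with an estimated correlation). Ribosomal proteins lay lower, with 0 of 79 passed by either adjustment, adjusted over the list alone included, and a median of -0.136 (camera, BH-adjusted p = 7.21e-14, and adjusted p = 0.57 with an estimated correlation). Ribosome biogenesis lay lower too, with 0 of 25 passed by either adjustment and a median of -0.154 (camera, BH-adjusted p = 1.67e-05, and adjusted p = 0.132 with an estimated correlation). Of 56 histone genes 1 fell, Hist1h1e, and 4 fell adjusted over the list alone, with a median of -0.24 (camera, BH-adjusted p = 8.06e-06, and adjusted p = 0.535 with an estimated correlation). At the same time the share of Rn45s in gene reads was lower in KO, as given above (two-sided exact permutation p = 0.1, the smallest possible). Ribosomal RNA was reduced with probes in these libraries, so this share may not follow the level of the precursor in the cells. T cell activation had 0 of 22 passed, 2 lower adjusted over the list alone and a median of -0.121 (camera, BH-adjusted p = 0.00146, and adjusted p = 0.59 with an estimated correlation). Nr4a1 had a log2 fold change of -0.19 and Nr4a3 of -0.06, and neither passed. The unfolded protein and integrated stress response had 0 of 16 passed and a median of -0.112 (camera, BH-adjusted p = 0.0366, and adjusted p = 0.597 with an estimated correlation).

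In metabolism, 1 of 23 glycolysis genes fell in activated KO cells, Tpi1, also adjusted over the list alone, and the list median was -0.128 (camera, BH-adjusted p = 0.00465, and adjusted p = 0.535 with an estimated correlation). By camera with BH adjustment, p was 0.873 for nuclear oxidative phosphorylation subunits (0 of 71 passed), 0.947 for the TCA cycle, 0.724 for fatty acid oxidation and 0.133 for glutamine and amino acid uptake. It was 0.648 for serine and one-carbon metabolism, 0.91 for the pentose phosphate pathway and 0.873 for cholesterol synthesis, with 0 members passed in each. The amino acid transporter gene Slc7a5 had a log2 fold change of -0.09 and the serine hydroxymethyltransferase gene Shmt2 of -0.09. Cytokines and chemokines had 0 of 19 passed (camera, BH-adjusted p = 0.058), immediate-early genes 0 of 15 with 1 higher and 3 lower adjusted over the list alone (camera, BH-adjusted p = 0.0973), and regulatory T cell genes 0 of 12 (camera, BH-adjusted p = 0.222). By camera with BH adjustment, p was 0.742 for T helper lineage genes, with 1 of 17 higher adjusted over the list alone, and 0.4 for inhibitory receptors, with 1 of 13 lower adjusted over the list alone. It was 0.742 for cytotoxic effector genes, 0.14 for cell cycle genes, 0.91 for other sirtuins and 0.91 for T cell markers. The genes near Sirt2 held 2 of 36 that rose, Fbxo17 and Fbxo27 (camera, BH-adjusted p = 0.648). Il2ra, the alpha chain of the interleukin 2 receptor, had a log2 fold change of -0.11 and Cd274, which encodes the ligand PD-L1, of 0.08, without passing. Cd8b1 had a log2 fold change of 0.36 and did not pass at 24 h (edgeR QL, BH-adjusted p = 0.798).

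At 24 h 30 genes passed, 20 higher and 10 lower in KO, each with no overlap between the libraries, against 12.9% of all tested genes without overlap and 10% by chance. At an unadjusted p below 0.05 there were 775, and DESeq2 called 38. Of the genes higher in KO 7 were shared with 0 h (Arrdc4, Fbxo17, Fbxo27, Gm10640, Ly6c1, Rhob and Txnip, of which Gm10640 lies outside the naming rule and is given because the count is shown), against 0.0237 for independent lists. Of those lower in KO 4 were shared (Sirt2, Pepd, Erf and the predicted gene Gm19897, outside the rule as well), against 0.0228. Of the 57 genes called at either time 50 had the same sign at both. Over all genes, which are not independent replicates, the fold changes at 0 h and 24 h had a Pearson r of 0.155 and a Spearman rho of 0.136. When each library of the groups compared was left out in turn, Fbxo17, Arrdc4, Fbxo27, Txnip, Slc43a2, Ly6c1 and Ifi27l2a passed each time. Xdh missed the threshold without WT replicate 2 (edgeR QL, BH-adjusted p = 0.126) and Pdlim4 without KO replicate 3 (edgeR QL, BH-adjusted p = 0.08). The other named genes, Tpi1 and Hist1h1e among them, missed it in 2 to 6 of the 6 refits, with BH-adjusted p of up to 0.203 and 0.355. Crem did not pass by DESeq2 (BH-adjusted p = 0.0624).

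**Figure D2:**
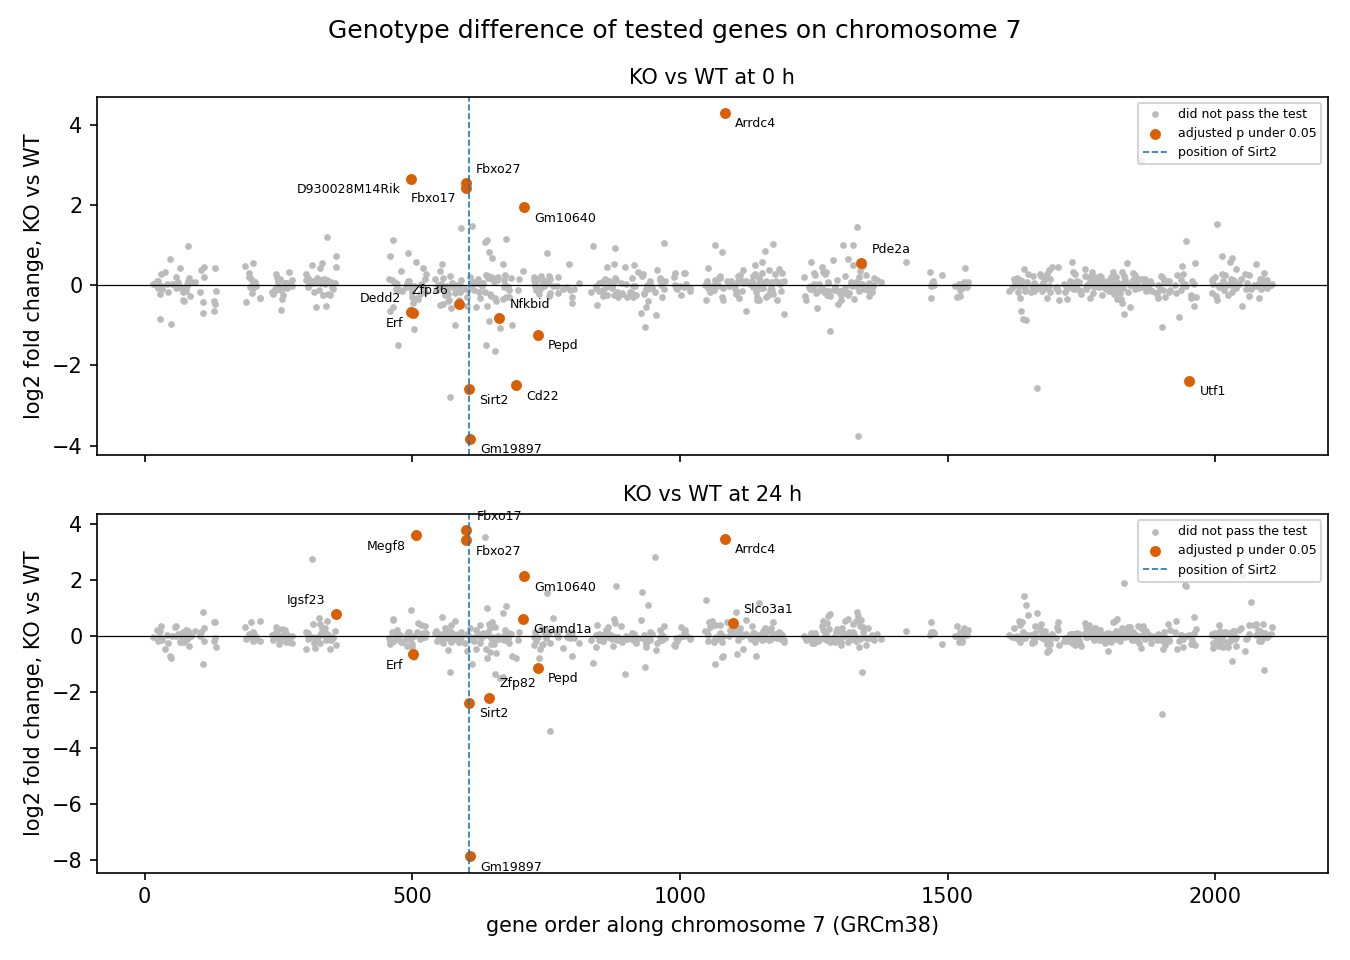
Log2 fold change of KO against WT (y axis) of each tested gene by its order along chromosome 7 in assembly GRCm38 (x axis, number of the gene), at 0 h in the upper and 24 h in the lower panel. Orange points passed the edgeR test with BH adjustment and grey points did not, the dashed line marks Sirt2, and fitted values of genes with hardly any read in a group, such as Gm19897, are no measure of size. Of the 166 tested genes within 150 genes of Sirt2, 14 passed at 0 h or 24 h.

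Of the other markers of spleen cells, of sex and of strain, Cd8b1, Cd22 and Irf4 passed between the genotypes at 0 h and 0 at 24 h (edgeR QL with BH adjustment). At 0 h the B cell list had a camera BH-adjusted p of 0.064 with 1 of 6 members fallen, Cd22, while Cd79a had a log2 fold change of 0.04 and Cd74 of -0.10. At 24 h the B cell list had 0.941 with 0 of 6 passed. Plasma cell markers had 0.886 at 0 h, where 1 of 6 fell, Irf4, which is also in the activation list, and 0.0643 at 24 h, where 0 passed and 2 were lower adjusted over the list alone. Macrophage and monocyte markers had 0.886 and 0.648, and neutrophil markers 0.711 and 0.648, by camera with BH adjustment, with 0 members passed and 1 of 4 neutrophil markers lower at 24 h adjusted over the list alone. The remaining markers were too few for a list test and, except for Cd8b1 at 0 h, did not pass as single genes. Of 8 stromal and endothelial markers 1 was tested, Pecam1, while Cdh5 was at 0.707 and Vwf at 0 CPM in WT 0 h. A single marker of a list therefore does not show that its cell type was present. At 0 h the log2 fold change was 0.39 for Klrb1c of natural killer cells, 0.48 for Ccr9 of dendritic cells, -0.76 for the erythroid marker Car2, 0.03 for the platelet marker Itga2b and 0.05 for the endothelial marker Pecam1, and -0.22 for Xist, which is expressed from the X chromosome of females. At 24 h it was -0.02 for Klrb1c, 0.14 for Ccr9, -0.18 for Car2, -0.86 for Itga2b, 0.35 for Pecam1 (which passed adjusted over the list alone, as its only tested member) and 0.08 for Xist. The strain genes at 24 h had a camera BH-adjusted p of 0.331 with 0 of 4 passed.

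The genes that differed between genotypes were concentrated around Sirt2. Named examples on chromosome 7 were Fbxo17 and Fbxo27, 5 and 6 genes from Sirt2, Zfp36 at 19, Zfp82 at 38, Nfkbid at 56, Cd22 at 87, Erf at 104, Dedd2 at 108 and Pepd at 128 genes. Within 150 genes of Sirt2, 14 of 166 tested genes passed at 0 h or 24 h (8.43%), against 37 of 10098 on other chromosomes (0.366%). Over chromosome 7 without Sirt2 it was 19 of 831 genes. Txnip lies on chromosome 3, and Myc, Nr4a2 and Irf4 lie on chromosomes 15, 2 and 13.

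Between 0 h and 24 h on anti-CD3 a large part of the measured genes changed in WT cells. No group was cultured for 24 h without the antibody. The effect of stimulation therefore cannot be told apart from that of time in culture after isolation, in WT or in KO. Chemokine, cytokine and amino acid supply genes were among the largest rises. Ccl22 was at least 117-fold higher at 24 h, Ccl1 rose by log2 6.89 (SE 0.310), Ccl3 by log2 5.86 (SE 0.509) and Ccl4 by log2 5.52 (SE 0.442), and Il13 had a ratio of 301 (95% exact counting interval 53.6 to 11900). Of the 19 cytokine and chemokine genes 14 rose and 2 fell, also adjusted over the list alone (median 2.06, camera, BH-adjusted p = 7.58e-09, and adjusted p = 0.194 with an estimated correlation). T cell activation genes rose in 18 and fell in 4 of 22 members, also adjusted over the list alone, with Irf4 at log2 3.99 (SE 0.0983), Egr2 at 2.75 (SE 0.205), the transferrin receptor gene Tfrc at 2.72 (SE 0.121) and Nr4a3 at 2.63 (SE 0.123). Their median was 1.13 (camera, BH-adjusted p = 1.11e-22, and adjusted p = 0.0158 with an estimated correlation). Interferon-stimulated genes rose in 17 and fell in 1 of 24 members, also adjusted over the list alone. Gbp2, an interferon-induced GTPase gene, went from 52.2 ± 8 to 1582 ± 251 CPM, and Iigp1 rose by log2 3.93, Oasl2 by 3.08 and Ifit3 by 2.91 (median 1.42, camera, BH-adjusted p = 1.19e-29, and adjusted p = 0.0114 with an estimated correlation). All of these genes passed by edgeR QL with BH adjustment.

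Genes of amino acid supply and ribosome biogenesis rose in WT. Of 15 genes of glutamine and amino acid uptake 10 rose and 2 fell, also adjusted over the list alone (median 1.44, camera, BH-adjusted p = 6.49e-14, and adjusted p = 0.0066 with an estimated correlation). The asparagine synthetase gene Asns rose by log2 5.44 (SE 0.350), Gpt2 by 5.06 (SE 0.488) and Slc7a5, a subunit of the large neutral amino acid transporter, from 74.2 ± 2.82 to 432 ± 29.5 CPM. The cystine transporter gene Slc7a11 had a ratio of 114 (95% exact counting interval 20 to 4530). The arginine transporter gene Slc7a3 was at least 60.1-fold higher, the cystathionine lyase gene Cth at least 44.3-fold higher, and the glycine transporter gene Slc6a9 had a ratio of 206 (95% exact counting interval 70.1 to 1000). Of 14 genes of serine and one-carbon metabolism 10 rose, also adjusted over the list alone, among them Shmt1 (log2 2.91), Psat1 (log2 2.19) and Shmt2 (log2 2.10) (median 0.945, camera, BH-adjusted p = 2.91e-09, and adjusted p = 0.0114 with an estimated correlation). Ribosome biogenesis rose in 24 of 25 members and in 25 adjusted over the list alone, such as Nop16 (log2 1.56), Nop56 (log2 1.29) and Nolc1 (log2 1.19) (median 0.878, camera, BH-adjusted p = 7.12e-14, and adjusted p = 0.0055 with an estimated correlation). Of the unfolded protein and integrated stress response 8 of 16 rose and 2 fell, with 9 and 2 adjusted over the list alone (median 0.264, camera, BH-adjusted p = 9.61e-05, and adjusted p = 0.201 with an estimated correlation). The stress genes Chac1 (log2 6.30), Atf3 (log2 4.97) and Trib3 (log2 3.39) led it. In glycolysis 5 of 23 rose and 3 fell, the same adjusted over the list alone, with the hexokinase gene Hk2 at log2 3.56 and the lactate transporter gene Slc16a1 at 0.94 against the glucose transporter gene Slc2a3 at -1.28 and Ldhb at -1.11 (camera, BH-adjusted p = 0.262). Cholesterol synthesis had 8 of 21 higher and 1 lower, the same adjusted over the list alone, with Idi1 at log2 1.39 (camera, BH-adjusted p = 0.138). Inhibitory receptors had 5 higher and 5 lower of 13, and 6 and 5 adjusted over the list alone, with Cd274 at log2 3.39, Lag3 at 2.00 and Tox at -1.52 (camera, BH-adjusted p = 0.15).

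Genes of the resting state fell in WT. Naive and quiescent T cell genes fell in 18 and rose in 4 of 24 members, also adjusted over the list alone, with Dapl1 at log2 -3.98 (SE 0.173), Igfbp4 at -2.79 (SE 0.0949) and Foxo1 at -1.21 (SE 0.0817), while the repressor gene Bach2 rose by 1.37. Their median was -0.668 (camera, BH-adjusted p = 7.88e-10, and adjusted p = 0.0066 with an estimated correlation). The Notch regulator gene Dtx1 fell by 5.6 on the log2 scale (SE 0.186). Immediate-early genes fell in 11 and rose in 3 of 15 members, and in 12 and 3 adjusted over the list alone, with Fos at log2 -5.26, Fosb at -5.20 and Dusp1 at -3.71 (median -1.92, camera, BH-adjusted p = 1.06e-24, and adjusted p = 0.0055 with an estimated correlation). Histone genes fell in 38 and rose in 6 of 56 members, and in 43 and 6 adjusted over the list alone, for example Hist1h3d at log2 -2.91 (median -1.25, camera, BH-adjusted p = 2.74e-07, and adjusted p = 0.201 with an estimated correlation). Ribosomal proteins fell in 45 and rose in 3 of 79 members, and in 49 and 3 adjusted over the list alone (median -0.265, camera, BH-adjusted p = 0.000127, and adjusted p = 0.593 with an estimated correlation). Of 71 oxidative phosphorylation subunits 21 fell and 4 rose, and 20 and 4 adjusted over the list alone, such as Ndufa3 at log2 -1.11 (camera, BH-adjusted p = 0.088). The TCA cycle had 9 of 24 lower and 2 higher, and 11 and 2 adjusted over the list alone, with Ogdh at log2 -0.55 (camera, BH-adjusted p = 0.15). Fatty acid oxidation had 7 of 26 lower and 1 higher, also adjusted over the list alone, with Cpt1a at log2 -1.17 (camera, BH-adjusted p = 0.261). Cell cycle genes fell in 10 and rose in 5 of 30 members, also adjusted over the list alone, with the cyclin gene Ccna2 at log2 -1.89 (camera, BH-adjusted p = 0.39). The pentose phosphate pathway had 1 higher and 2 lower of 10, also adjusted over the list alone, with Prps1 at log2 0.93 and Prps2 at -1.04 (camera, BH-adjusted p = 0.729). T helper lineage genes rose in 5 and fell in 8 of 17, also adjusted over the list alone, with Il12rb2 at log2 2.16 and Cxcr5 at -3.10 (camera, BH-adjusted p = 0.399). Regulatory T cell genes rose in 5 and fell in 4 of 12, and in 5 and 5 adjusted over the list alone, with Il2ra at log2 1.87 and Nrp1 at -1.49 (camera, BH-adjusted p = 0.736). Of the other sirtuins 1 of 6 fell, Sirt7 at log2 -1.57, also adjusted over the list alone (camera, BH-adjusted p = 0.258).

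Markers of other cells moved along with these lists. In WT the plasma cell marker Igj fell from 113 ± 29.8 to 2.06 ± 0.513 CPM, the B cell markers Cd79a and Cd22 by log2 values of -1.90 and -3.61, and the natural killer cell marker Klrb1c by -4.60. The dendritic cell marker Ccr9 fell by log2 -3.01 and Cd8b1 by -0.93, and the neutrophil marker Mmp9 was at least 50.5-fold lower. Only 2 of 9 dendritic cell markers and 4 of 10 neutrophil markers had enough reads to be tested. In WT 0 h Itgax of the first list was at 0.663 CPM and S100a8 of the second at 0.231 CPM. Ccr9 and Mmp9 alone therefore do not show that such cells were present or lost. Of 6 B cell markers 4 fell (camera, BH-adjusted p = 0.0642). T cell markers fell in 8 of 11 members, also adjusted over the list alone, with Thy1 at log2 -2.60, Cd4 at -1.50 and Cd3e at -0.97 (median -0.809, camera, BH-adjusted p = 8.95e-11, and adjusted p = 0.0126 with an estimated correlation). Cytotoxic effector genes rose in 2 and fell in 8 of 11, and in 3 and 8 adjusted over the list alone, with Gzmb at log2 1.79 and Prf1 at -1.76 (camera, BH-adjusted p = 0.15). Genes near Sirt2 rose in 7 and fell in 10 of 36, also adjusted over the list alone, with Zfp36 at log2 -1.92 (median -0.238, camera, BH-adjusted p = 0.0395, and adjusted p = 0.254 with an estimated correlation). In WT 4470 genes passed, 2217 higher and 2253 lower at 24 h, and 641 rose and 813 fell by at least 2-fold. Leaving out any 1 library, or DESeq2 with 4255 genes, gave a count within 1.5 times of this.

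In KO cells, chemokine and amino acid supply genes were among those that rose most. Ccl22 was at least 159-fold higher, Chac1 at least 131-fold and Slc7a3 at least 43.8-fold, and Cth at least 42.2-fold and the dehydrogenase gene Bdh2 at least 39.4-fold. Ccl1 rose by log2 7.51 (SE 0.321), Ccl4 by 7.08 (SE 0.521), Il13 by 5.92 (SE 0.502), Asns by 6.34 (SE 0.376), Irf4 by 4.11 (SE 0.101), Nr4a3 by 3.08 (SE 0.126) and Nr4a2 by 2.90 (SE 0.133). Gbp2 went from 57.6 ± 8.53 to 1762 ± 116 CPM and Slc7a5 from 58.0 ± 4.27 to 405 ± 28.4 CPM. Among the falls were Dtx1 (log2 -5.38, SE 0.187), Fos (log2 -5.29, SE 0.131), Klrb1c (log2 -5.01, SE 0.374) and Fosb (log2 -4.67, SE 0.143). Cd72, a B cell surface gene, was lower by a ratio of 85.0 (95% exact counting interval 23.3 to 706) and Mmp9 by 33.3 (11.2 to 164). Lists that rose were interferon-stimulated genes (19 of 24 higher and 0 lower, 20 and 1 adjusted over the list alone, camera, BH-adjusted p = 2.51e-35) and T cell activation (18 of 22 higher and 4 lower by either adjustment, adjusted over the list alone included, BH-adjusted p = 4.9e-27). Glutamine and amino acid uptake (11 of 15 higher, 2 lower, camera, BH-adjusted p = 4.33e-14), ribosome biogenesis (24 of 25, BH-adjusted p = 3.7e-13) and serine and one-carbon metabolism (9 of 14, BH-adjusted p = 6.71e-10) rose too, with equal counts adjusted over the list alone. With an estimated correlation these had adjusted p = 0.0064, adjusted p = 0.00809, adjusted p = 0.00411, adjusted p = 0.00411 and adjusted p = 0.0064 in the same order. Cytokines and chemokines (14 of 19 higher, 2 lower, BH-adjusted p = 1.55e-10) had adjusted p = 0.119 with an estimated correlation. The unfolded protein and integrated stress response (7 of 16 higher, 2 lower, BH-adjusted p = 0.000148) had adjusted p = 0.187 with an estimated correlation.

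Lists that fell in KO were immediate-early genes (11 of 15 lower and 3 higher, camera, BH-adjusted p = 3.19e-21), T cell markers (9 of 11, BH-adjusted p = 4.52e-13) and naive and quiescent genes (18 of 24 lower and 3 higher, BH-adjusted p = 9.75e-11), with equal counts adjusted over the list alone. With an estimated correlation they had adjusted p = 0.00411, adjusted p = 0.00753 and adjusted p = 0.00411. Histones (44 of 56 lower and 4 higher, the same adjusted over the list alone, BH-adjusted p = 1.46e-11) had adjusted p = 0.0893 with an estimated correlation. Ribosomal proteins (52 of 79 lower and 3 higher, 55 and 3 adjusted over the list alone, BH-adjusted p = 1.03e-06) had adjusted p = 0.521 with an estimated correlation. Oxidative phosphorylation subunits (24 of 71 lower and 3 higher, the same adjusted over the list alone, BH-adjusted p = 0.0398) had adjusted p = 0.633 with an estimated correlation. Dapl1 fell by 3.96 on the log2 scale, Igfbp4 by log2 -2.65, Foxo1 by -1.33, Dusp1 by -3.59, Hist1h2ab by -2.92, the proliferation marker gene Mki67 by -2.06 and Ndufa3 by -0.90. By camera with BH adjustment, p was 0.332 for glycolysis (6 of 23 higher, such as Hk2 at log2 4.35, and 3 lower), 0.239 for the TCA cycle (8 of 24 lower), 0.141 for fatty acid oxidation (8 of 26 lower and 1 higher) and 0.189 for cholesterol synthesis (10 of 21 higher and 2 lower). It was 0.561 for the pentose phosphate pathway, 0.144 for cytotoxic effector genes, 0.239 for inhibitory receptors, 0.808 for regulatory T cell genes, 0.332 for T helper lineage genes, 0.14 for cell cycle genes (13 of 30 lower and 4 higher), 0.239 for other sirtuins and 0.0517 for genes near Sirt2. Among markers of other cells, Igj fell from 134 ± 18 to 1.97 ± 1.08 CPM, Cd79a by log2 -2.32, Ccr9 by -3.35 and Cd8b1 by -1.41, and 5 of 6 B cell markers fell (camera, BH-adjusted p = 0.189). In KO 4435 genes passed, 2129 higher and 2306 lower, with 657 risen and 815 fallen by at least 2-fold, and DESeq2 called 4203.

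**Figure D3:**
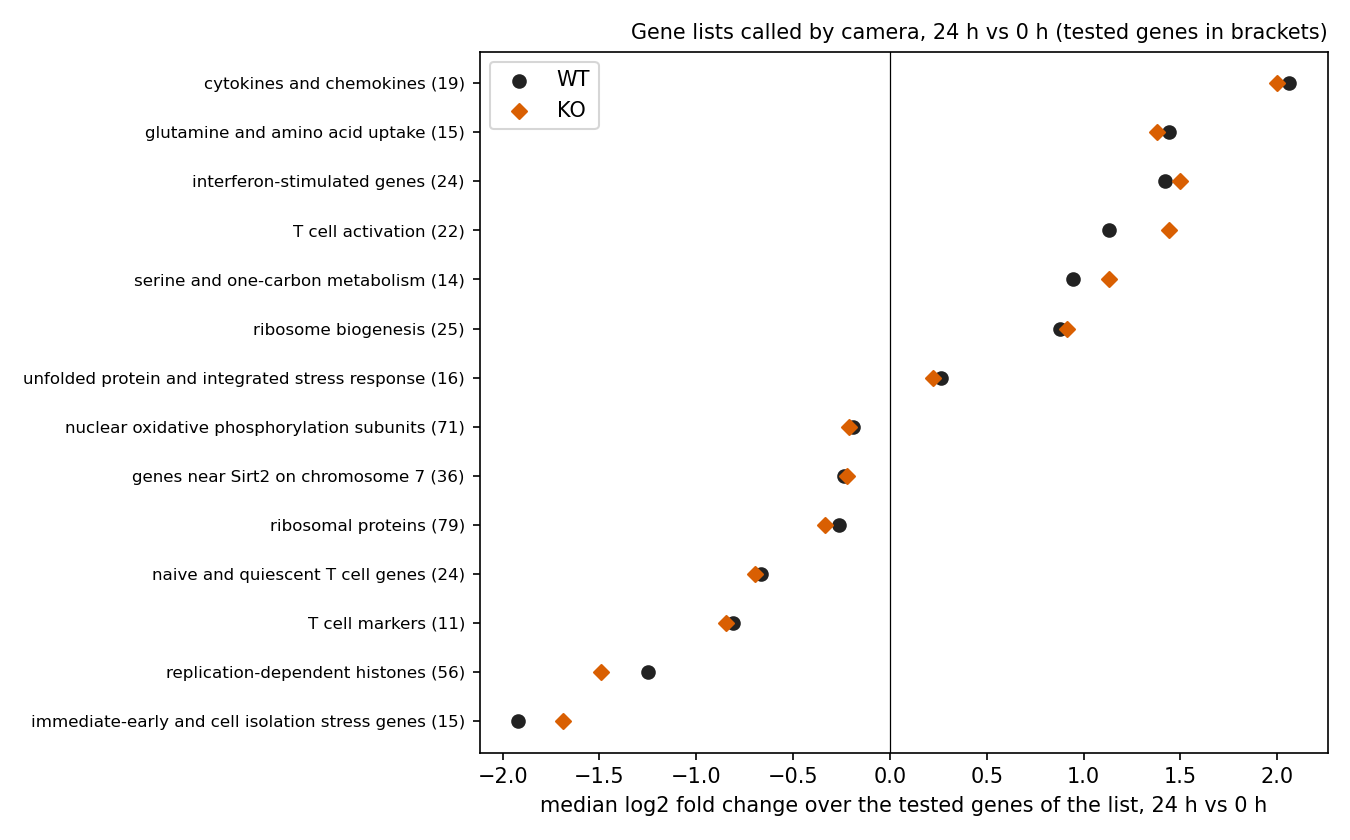
Median log2 fold change of gene lists (rows of the plot, x axis in log2 units) for 24 h against 0 h, in WT and in KO. Lists of interferon-stimulated genes (median 1.42 in WT and 1.5 in KO), cytokines and chemokines (2.06 and 2.00) and amino acid uptake (1.44 and 1.38) lay to the right, and immediate-early genes (-1.92 and -1.69) and histones (-1.25 and -1.49) to the left in both genotypes.

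WT and KO cells shared a large part of the genes that changed between 0 h and 24 h on anti-CD3. Of the genes called higher at 24 h 1678 were shared between WT and KO (430 for independent lists), and of those called lower 1791 (473 for independent lists). Over all genes, which are not independent replicates, the fold changes had a Pearson r of 0.871 and a Spearman rho of 0.826. The interaction of genotype and time, which tests whether the responses differ, called 1 gene, the linker histone gene Hist1h1e, with an interaction of log2 -0.71 (SE 0.134, edgeR QL, BH-adjusted p = 0.0442), and 575 genes had an unadjusted p below 0.05. At 0 h Hist1h1e did not pass between genotypes (log2 0.29, edgeR QL, BH-adjusted p = 0.288), and at 24 h it was lower in KO, as given above. DESeq2 called 1 gene as well, while limma-voom, DESeq2 size factors and upper-quartile factors called 0. Without any 1 of 10 of the 12 libraries Hist1h1e did not pass (edgeR QL, BH-adjusted p of up to 0.258 without WT 0 h replicate 1), and the exceptions were KO 24 h replicate 2 and WT 0 h replicate 3. Sirt2 itself had an interaction of log2 0.21, Nr4a3 of 0.45 and Slc7a5 of 0.27, without passing.

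By list, the interaction was lower for histones, with a median of -0.291 over 56 genes, 1 passed and 3 lower adjusted over the list alone (camera, BH-adjusted p = 5.16e-07), and for ribosomal proteins, with a median of -0.074 (camera, BH-adjusted p = 0.0344), each with adjusted p = 0.876 with an estimated correlation. It was higher for T cell activation, with a median of 0.119 and 1 of 22 higher adjusted over the list alone (camera, BH-adjusted p = 0.0133), and for interferon-stimulated genes, with a median of 0.108 and 2 of 24 higher adjusted over the list alone (camera, BH-adjusted p = 0.0242), each with adjusted p = 0.876 with an estimated correlation. Immediate-early genes had a median of 0.127 (camera, BH-adjusted p = 0.0417, and adjusted p = 0.876 with an estimated correlation). None of these lists passed with fry. No list of metabolism passed for the interaction by camera with BH adjustment.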

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

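In this part the test without the genes of chromosome 7 was chosen only after the result was seen, and the others were planned. The check of opposite directions covered 231 named genes.

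Hist1h1e, a linker histone gene, is listed because its genotype difference changed between the time points, with an interaction of log2 -0.71 (edgeR QL, BH-adjusted p = 0.0442). It is listed also because KO and WT libraries did not overlap at either time and differed in opposite directions, as 1 of the 231 named genes checked. Chance gives no overlap in 10% of genes at each time. Hist1h1e was among the named genes because it had passed at 24 h and for the interaction, so the check adds no separate evidence. At 0 h the KO libraries had 171, 155 and 165 CPM of Hist1h1e and the WT libraries 132, 122 and 150 CPM, and at 24 h KO had 107, 133 and 122 CPM and WT 163, 154 and 168 CPM. The gene overlaps Hist1h2be and has close copies, so its reads are uncertain. In 20 of 100 splits of the libraries, the real one included, at least 1 gene was called for the interaction. The real value was 1 and the highest other was 65, so chance is not excluded. The split with 65 calls exchanges the genotypes at one time, so that it measures the sum of both genotype differences, which is a structure of these libraries.

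Of the gene lists, 5 are listed because their change from 0 h to 24 h differed between WT and KO by the interaction test with camera. The medians were -0.291 for histones, -0.074 for ribosomal proteins, 0.119 for T cell activation, 0.108 for interferon-stimulated genes and 0.127 for immediate-early genes. With an estimated correlation each had a BH-adjusted p of 0.876, fry called 0 of them, and without the genes of chromosome 7 the immediate-early list had a camera BH-adjusted p of 0.249. For the lists, 43 of 100 splits called at least as many, with 5 in the real split and 15 as the highest other, and chance is not excluded.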

How the results depend on the processing

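Leaving out the genes of chromosome 7 was chosen after seeing the data, and the other alternatives were planned. No named gene that had passed, Sirt2 included, reversed its direction under DESeq2, DESeq2 size factors, the replicate block or single libraries left out. Sirt2 stayed past the threshold in these settings, with log2 -2.80 to -2.43 at 0 h and -2.75 to -2.20 at 24 h over single libraries left out. The balance of calls did change sides: the higher ones were 34.2% at 0 h, 50% with only the 2 groups and 51.9% without WT_0h replicate 3, and without a filter 52.1% in place of 49.6% over time in WT and 51.2% in place of 48% in KO. With upper-quartile factors these were 42.2% and 42.8%, and with the filter at 1 CPM 51.8% and 51.6%. Without single 0 h libraries they were 50.8% to 51.9% in WT and 50.8% to 51.6% in KO, and without genes of chromosome 7 51.6% in both. The counts between genotypes depended on single libraries. At 0 h 17 to 33 genes passed in place of 38, with 17 without KO_0h replicate 3, 22 without KO_0h replicate 2 and 25 without WT_0h replicate 1. At 24 h 14 to 31 passed in place of 30, with 14 without WT_24h replicate 2, 16 without KO_24h replicate 1 or KO_24h replicate 3, and 18 without KO_24h replicate 2. Fewer samples lower the power by construction. Over time 3861 to 4171 genes passed in WT and 3676 to 4100 in KO. For the interaction 0 to 1 passed, with 0 in 10 of the 12 refits (edgeR QL, 575 at an unadjusted p below 0.05 with all libraries, 1 by DESeq2). It was 0 under limma-voom, DESeq2 size factors, upper-quartile factors, the filter at 1 CPM, structural RNA left out, the replicate block and the replicate block by genotype, and 3 without a filter, of which 1 was shared. The cause was not tested. Without a filter 59 genes passed at 0 h, the 38 among them, and with only the 2 groups compared 24, all shared. Without chromosome 7, which held 15 and 13 of the called genes, 13 passed at 0 h and 14 at 24 h, all shared, so that 10 and 3 genes of other chromosomes were lost. Taking out that many called genes raises the Benjamini-Hochberg adjusted p of the remaining genes near the threshold by construction. Whether anything else added to the losses was not tested. DESeq2 called 47, 38, 4255, 4203 and 1 genes, in the order 0 h, 24 h, WT, KO and interaction. Gene lists depended on the correlation between genes. In that order camera called 6, 8, 13, 13 and 5, with an estimated correlation 0, 0, 8, 8 and 0, and fry 1, 0, 22, 25 and 0. For the 6 lists called at 0 h the estimated correlation lay above the preset 0.01. It ran from 0.0358 for naive and quiescent genes to 0.502 for ribosomal proteins. Why fry differed was not tested. In KO over time 20 lists passed without a filter. With 1 library left out, lists ranged from 5 to 9, 6 to 11, 12 to 14, 12 to 14 and 2 to 6. For the interaction there were 2 without WT_24h replicate 2, and 3 without KO_0h replicate 1, WT_0h replicate 1, WT_24h replicate 1, KO_0h replicate 2 or KO_24h replicate 3. Histones passed for the interaction in 12 of 12 refits, T cell activation in 8, interferon-stimulated genes and ribosomal proteins in 6 and immediate-early genes in 5. At 0 h glycolysis passed in 2 of 6 refits and not without KO_0h replicate 1, WT_0h replicate 1, KO_0h replicate 2 or WT_0h replicate 2 (camera, BH-adjusted p of up to 0.312), and ribosomal proteins in 4 of 6, not without KO_0h replicate 3 or WT_0h replicate 3 (up to 0.154), while the other 4 lists passed in 6. At 24 h the stress response list failed without KO_24h replicate 1, KO_24h replicate 3 or WT_24h replicate 3, T cell activation without KO_24h replicate 1 or WT_24h replicate 3 (both up to 0.642), and glycolysis without WT_24h replicate 3 (0.184). Over time, oxidative phosphorylation in KO failed without KO_0h replicate 1 or KO_24h replicate 1 (up to 0.139), and genes near Sirt2 in WT without WT_24h replicate 1 or WT_24h replicate 2 (up to 0.0627). Some lists that had not passed did so in 1 to 5 refits. Cytokines and chemokines at 24 h (0.058) passed without KO_24h replicate 1 or WT_24h replicate 3 (range 6.21e-10 to 0.677), with the replicate block (0.007) and without chromosome 7 (0.0387), and had 0.751 with an estimated correlation. Without chromosome 7 glycolysis at 0 h did not pass (0.0575). At 24 h immediate-early genes (0.0387) and plasma cell markers (0.0405) passed without chromosome 7, and for the interaction cell cycle genes passed with DESeq2 size factors (0.0478), the replicate block (0.0362) and no filter. The cause was not tested. Across all groups the replicate numbers showed no pairing of the libraries. Residuals of the same number correlated with r of -0.0884 to 0.0934 over 18 pairs. Of 12 libraries 0 correlated best with their own number in every other group. Within a genotype, the 6 pairs of the same number at 0 h and 24 h had r of -0.00224 to 0.0934 (median 0.0407). Pairs of different numbers had r of -0.131 to 0.129 (median -0.00254). A weak pairing over time within a genotype is therefore not excluded. With the replicate block 4 named genes did not pass at 0 h (BH-adjusted p of 0.056 for Rab11fip3, 0.0572 for Arc, 0.0648 for Nr4a2 and 0.0844 for Irf4), 3 at 24 h (among them 0.058 for Adamtsl4 and 0.0575 for Crem), 1 over time in WT, 2 in KO, and Hist1h1e for the interaction (0.0835). On simulated data 1.5-fold changes were recovered in 58.2% of genes at 0 h and 40.3% at 24 h, and whether depth, the number of libraries or their spread limits this was not tested.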

Other observations

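In this part the tests on gene position, on chromosome 7 members, on Foxp3, and on Txnip and Arrdc4 were chosen only after the result was seen. So were their windows of 150, 25 and 50 genes and the limit of 400 genes. The heat-shock test was written before the values of its 4 genes were seen, but after the list that holds them had been seen to be lower. The splits of the libraries were planned.

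Splits of the same libraries show what groupings other than the real one gave. For KO against WT at 0 h 38 genes were called in the real split and at most 2 in any other, and at 24 h 30 and at most 3, each the 1 split of 10 with as many. Over time the real split called 4470 genes in WT and 4435 in KO, and the highest other 0 in each, again 1 of 10. Every other split over time mixes both times within a group, which adds the time difference to the spread. Few or no calls in these splits are thus built in and do not measure what chance gives. The genotype splits mix the genotypes in the same way. For gene lists at 0 h 3 of 10 splits called as many, with 6 in the real split and 9 as the highest other. At 24 h 5 of 10 did, with 8 and 14. Over time it was 1 of 10 in WT, with 13 and 12, and 3 of 10 in KO, with 13 and 13. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The list calls between genotypes by camera were matched or exceeded by other splits.

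The first pattern is the gathering of called genes around Sirt2. A chromosome segment around the knockout allele that differs between the KO and WT mice is a candidate explanation, since genes within 150 genes of Sirt2 had an odds ratio of 25 for being called (12.2 to 48.5, two-sided Fisher exact p = 3.71e-14). Loss of SIRT2 acting on genes wherever they lie, as the whole cause, is argued against by an odds ratio of 6.36 for chromosome 7 without Sirt2 (3.44 to 11.4, two-sided Fisher exact p = 1.28e-08), and an effect of the allele on direct neighbours only by one of 21.9 at 26 to 150 genes (9.49 to 46.2, two-sided Fisher exact p = 3.63e-10). The 19 called genes of chromosome 7 include the 14 within 150 genes of Sirt2, so these odds ratios rest largely on the same calls and are not separate evidence. Neighbouring genes can be regulated together, which these tests treat as independent. Differences in Fbxo17, Fbxo27, Nfkbid, Cd22, Zfp36, Erf and Pepd may therefore come from the segment and not from SIRT2, which stays a hypothesis found and tested on the same data.

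The second pattern is the lower level of T cell activation and immediate-early genes in KO at 0 h, which is not firm, since both lists had adjusted p = 0.159 with an estimated correlation. Of the 22 and 15 tested members 21 and 13 lie elsewhere than on chromosome 7, with medians of -0.29 and -0.274. The lower level was thus not confined to members on chromosome 7. Without these members the larger BH-adjusted camera p of the lists was 4.71e-06 at the preset correlation. With so few members on chromosome 7, leaving them out could hardly change the lists, so this p-value decides little. Weaker isolation stress in the KO cells cannot be told apart from the other explanations, because the heat-shock genes Hspa1a (log2 -2.06), Hspa1b (log2 -2.12), Hsph1 (log2 -0.49) and Dnajb1 (log2 -0.50), with a median of -1.28, are members of the list seen to be lower, and none passed (edgeR QL, BH-adjusted p of 0.17, 0.636, 0.0999 and 0.0974). A smaller share of regulatory T cells cannot be told apart either, because the Foxp3 value of -0.24 has a 95% interval of -0.517 to 0.0276, which holds both 0 and the list median of -0.294. A direct effect of Sirt2 loss, the difference that the design names, stays open too.

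The third pattern is the higher level of Txnip and Arrdc4 in KO at both times. Txnip lies on chromosome 3 and so outside the segment around the knockout allele, but an effect of the segment's genes on Txnip was not tested. For Arrdc4, on chromosome 7 at 478 genes from Sirt2, it cannot be told apart from an effect of SIRT2, because 1 of the 44 tested genes within 50 genes of it was called, Slco3a1, and no marker of the segment's ends was used here. A larger share of naive cells is argued against as the whole cause of the Txnip rise at 0 h. The other 23 naive and quiescent genes had a median of 0.0597 (SD 0.132 over genes, not libraries) against 1.04 for Txnip. Txnip was set against its list after its rise had been seen, and Arrdc4 was not compared. An effect of Sirt2 loss on Txnip stays a hypothesis, as does any other difference between the KO and WT mice.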
